A study of Oryza sativa with 2 samples.

How the data were processed

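Total RNA was sequenced from 2 libraries of Minghui 63 rice grown under 14 h of light at 32 °C and 10 h of dark at 28 °C, after seeds were soaked for 72 h at 37 °C. Ribosomal RNA was removed from 2 µg of RNA and a strand-marking kit was used, per the labels' protocols. Reads were paired and 150 bp long. Each library had a table of counts per gene and a table with length, count, FPKM and upper-quartile FPKM. The submitters' processing notes name Trimmomatic, HISAT2 and HTSeq without versions. The genome build, the annotation and the strand setting of the counting were not given in the sources used here.

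The count values are raw whole numbers per gene, as deposited, and the count column of the second table equals the first for all 57342 shared identifiers in both libraries. FPKM was computed by the authors, per the file headers, and equals the CPM over the gene total divided by the length in kb, recomputed here to within 5e-06. The Spearman correlation across genes of count with FPKM times length was 0.999 in both libraries. The column named upper-quartile FPKM was not used. Its divisor was 2491 in both libraries, which is the upper quartile of the lengths and not of the counts (27 and 28), so it keeps the depth difference between the libraries. OrsaiCp60 has counts and no FPKM row. Of the lengths, 74.3% were multiples of 3, more than whole transcripts would give, so part of the models hold coding sequence alone and the lengths are not of 1 kind.

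The counting summary lines name no gene and were kept out of library sizes and tests. They held entries without a feature (8.08% and 7.95% in libraries 1 and 2) and with more than a single alignment (27.7% and 25.8%). They also held entries not aligned (6.15% and 4.31%), of low quality (0.958% and 1.01%) and ambiguous (0.0330% and 0.0338%). These shares are of the sum of gene counts and summary lines. A fragment with several alignments may have entered that sum more than once, so they need not be shares of fragments.

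Replicate agreement was tested per identifier with a two-sided exact binomial test on the counts, with the expected share from TMM-scaled library sizes (edgeR factors 1.009 and 0.991), over identifiers with 10 or more counts in sum, with Benjamini-Hochberg adjustment at 0.05. Log2 ratios used a pseudocount of 0.5. The dispersion between libraries came from edgeR's common dispersion after its expression filter. DESeq2 was used for alternatives only. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Its size factors were exactly 1 and 1, because the median ratio fell on identifiers with equal counts, which were 2934 of the 26340 with counts in both libraries. Expressed genes were those with an FPKM of 1 or more in both libraries. Chromosome numbers were read from the identifiers. Shares carry 95% Wilson or Clopper-Pearson intervals. Intervals and limits cover counting error only, since no molecular identifiers were used.

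On simulated data with sampling noise only, the exact binomial test recovered 43.0% of identifiers changed 1.5-fold and 69.0% of those changed 2-fold, and 83.7% and 100% of those with a mean of 100 or more counts, with 4 unchanged identifiers called among 19838 tested. With the estimated spread between libraries added, it recovered 38.0% and 69.0%, and 73.5% and 97.9% of those with a mean of 100 or more counts, and it called 209 unchanged identifiers among 19854 tested. The dispersion estimate returned 3.65% where 3.60% was set.

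The named identifiers were fixed before the data were examined as the highest by mean FPKM, the highest among organelle genes, and the largest library differences among identifiers with a mean of 100 or more counts and an adjusted p under 0.05. At most 2 per part or direction are printed, because no source paired identifiers with names. The 15 gene lists fixed beforehand, including morning and evening clock genes, matched 0 identifiers, so list levels and the clock comparison were not run. Alternatives covered scaling, count filters, pseudocounts, FPKM floors and leaving out either library.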

Results

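The RNA of young rice plants was measured in 2 libraries of total RNA depleted of ribosomal RNA. The plants were Minghui 63, a parental line of the widely grown hybrid Shanyou 63. They were 2 weeks old and were collected at 8:00. The sample label calls the material seedling and the extraction protocol names leaves. The RNA measurement stood beside maps of RNA contacts with chromatin that carries H3K4me3, a histone mark found at active promoters. Those maps were not analysed here. The libraries form a single group, so no treatment, tissue or time could be compared, and each comparison was made between the libraries or between sets of identifiers. The labels do not say that the libraries came from separate plants, so their spread may be technical.

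Library 1 held 18096722 gene counts and library 2 held 18799901. These were 57.0% of 31722418 and 60.9% of 30873154, the sums of gene counts and counting summary lines. A fragment with several alignments may have entered those sums more than once. The 57343 gene identifiers fall into an MH series of 57185 and an Orsai series of 158. The MH identifiers carry a chromosome number from 1 to 12, except 44 that carry none. The Orsai identifiers are divided by their prefix into OrsaiCp, OrsaiPp, OrsaiPr and OrsaiPt. No source used here paired the identifiers with gene names, and 0 of them matched the reference gene table, so genes are given by identifier.

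The 158 Orsai identifiers held 52.6% of the gene counts in library 1 and 53.0% in library 2. The 65 OrsaiCp identifiers took 49.7% of the counts in library 1 and 50.4% in library 2. The 54 OrsaiPp identifiers took 2.85% and 2.59%. The MH identifiers, which make up nearly the whole table, took 47.4% and 47.0%. OrsaiCp01 alone took 40.8% of the counts in library 1 (95% Clopper-Pearson interval 40.76% to 40.81%) and 41.7% in library 2 (41.73% to 41.77%). Such intervals cover counting error only. The difference between the libraries in this share was larger than those intervals.

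**Figure D1:**
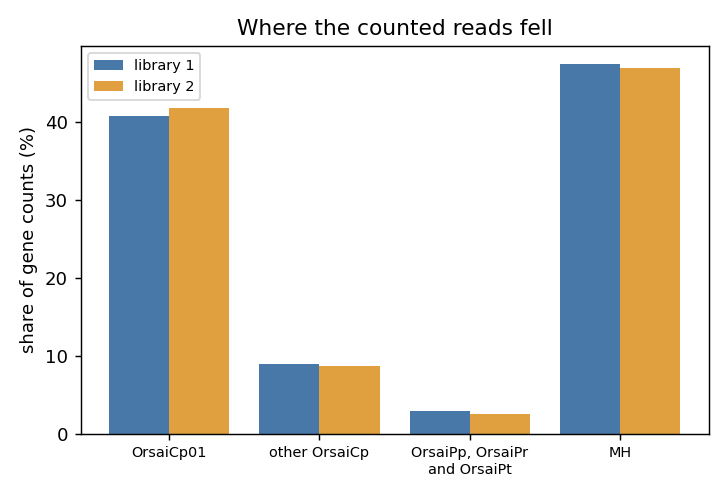
Share of the gene counts, in percent, that fell on OrsaiCp01, on the other OrsaiCp identifiers, on the remaining Orsai identifiers and on the MH identifiers, with a bar for each of the 2 libraries. OrsaiCp01 held 40.8% and 41.7%, close to the 47.4% and 47.0% of all MH identifiers together.

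The highest expression levels belonged mostly to OrsaiCp identifiers. OrsaiCp01 reached an FPKM of 388577 ± 6422 (SD, n = 2), and OrsaiCp36 followed with 24912 ± 199 (SD, n = 2). Among the 20 identifiers with the highest mean FPKM, 13 were OrsaiCp, 1 was OrsaiPp and 6 were MH. The highest MH identifier was MH11g0663900, at rank 7, with an FPKM of 14231 ± 112 (SD, n = 2). It belongs to those 20 by the rule fixed beforehand, but it is printed beyond the limit of 2 identifiers and was singled out for that after its values were seen. The median FPKM of the OrsaiCp identifiers was 590 in library 1 and 568 in library 2, against 50.6 and 49.8 for OrsaiPp and 0.0372 and 0.0281 for MH. Each FPKM was scaled by a gene total of which OrsaiCp01 made up 40.8% and 41.7%.

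Counts were concentrated in few identifiers. The 10 identifiers with most counts held 50.2% of library 1 and 50.8% of library 2, and the top 100 held 64.0% and 64.5%. Of the top 10, 9 were the same in both libraries, and of the top 100, 97 were the same. With the Orsai identifiers left out, the top 10 MH identifiers held 10.8% and 10.9% of the MH counts, and the top 100 held 29.7% and 30.0%.

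Of 57342 identifiers with an FPKM value, 13403 (23.4%) reached an FPKM of 1 in both libraries. These were 13298 MH and 105 Orsai identifiers. At an FPKM of 100 or more in both libraries 367 remained, of which 62 were Orsai, and at 1000 or more 61 remained, of which 29 were Orsai. Of all 57343 identifiers, 20749 (36.2%) had no count in either library. A count of 0 allowed up to 0.166 CPM in library 1 and 0.160 in library 2, for reads with a single alignment. Reads with more than a single alignment were left uncounted, so the limit need not hold for genes in repeats or with copies. These identifiers were not detected at this depth by such counting.

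The expressed share differed between chromosomes. It was highest on chromosome 3, at 31.1% (95% Wilson interval 29.9% to 32.3%), followed by chromosome 2 at 28.9% and chromosome 1 at 27.8%. It was lowest on chromosome 11, at 14.6% (13.7% to 15.7%), and chromosomes 9 and 10 were also low, at 19.0% and 18.5%. Over the 12 chromosomes, 13297 of 57141 MH identifiers were expressed. A permutation test of the chi-square statistic (717, 11 degrees of freedom) gave p = 1e-05, the smallest that 100000 permutations can give. Identifiers are not independent of each other, so this p overstates the evidence and the Wilson intervals are likely too narrow. The test describes this table of genes and not a population of plants.

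**Figure D2:**
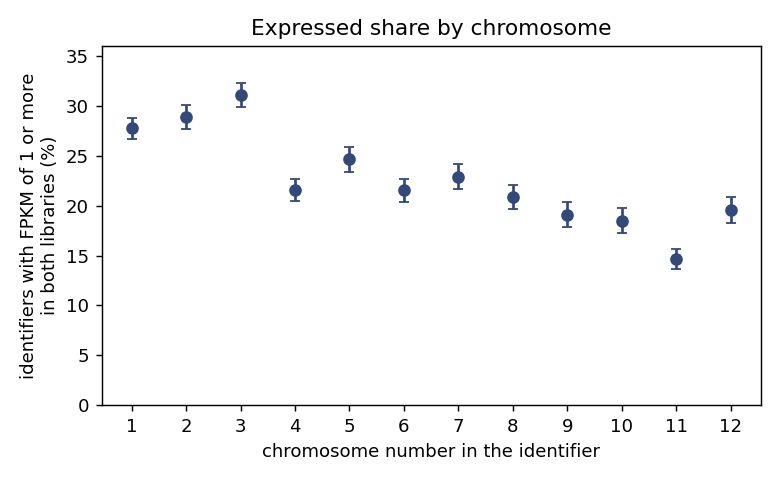
Share of MH identifiers with an FPKM of 1 or more in both libraries, in percent, for each chromosome number carried by the identifiers. Points are shares and bars are 95% Wilson intervals, which treat identifiers as independent and are likely too narrow. Chromosome 3 lies highest at 31.1% and chromosome 11 lowest at 14.6%.

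The libraries were compared with each other to see how far they differed beyond sampling noise. Across 57342 identifiers, log2(FPKM + 1) gave Pearson r = 0.995 and Spearman rho = 0.858, and across the 13403 expressed identifiers rho was 0.986. These coefficients are across genes, which are not independent replicates. The variation between the libraries beyond counting noise, from edgeR's common dispersion over 17027 identifiers, was a coefficient of variation of 3.63%. It is a single value for all identifiers and need not describe the typical one. The chi-square of each identifier's counts against the expected share averaged 2.32 over 19770 identifiers. Its median was 0.593, where sampling noise alone gives 0.455.

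Of 19770 identifiers with 10 or more counts in sum, 134 had an adjusted p under 0.05 in a two-sided exact binomial test with Benjamini-Hochberg adjustment. In simulated libraries with the estimated spread between libraries, the same test called 209 unchanged identifiers among 19854. That spread was estimated from these libraries, so the simulated count is no independent check of the 134, and it does not bear on the size of single differences. Of the 134, 58 were higher in library 1 and 76 were higher in library 2. That split moved with the scaling of the libraries. It was 38 and 151 with DESeq2 size factors and 91 and 34 with total counts. Only 22 of the 134 differed by 1.5-fold or more, 19 higher in library 1 and 3 higher in library 2. By series, the 134 were 110 of 19654 MH identifiers, 15 of 62 OrsaiCp, 6 of 40 OrsaiPp and 3 of 4 OrsaiPr. Those at 1.5-fold or more were 18 MH, 0 OrsaiCp, 1 OrsaiPp and 3 OrsaiPr. The test calls smaller differences where counts are higher, so the shares called do not rank the series by how much they differed. The test sets sampling noise as its null and says that the libraries differ, not that conditions do.

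The most unequal identifiers with a mean of 100 or more counts were few. MH04g0248400 had 168 counts in library 1 and 33 in library 2, 5.13-fold higher (95% interval 3.56 to 7.79, log2 ratio 2.36). MH05g0279900 had 818 and 374 counts, 2.23-fold higher (1.97 to 2.53). In the other direction, MH03g0044000 had 4096 counts in library 1 and 9637 in library 2, 2.31-fold higher in library 2 (2.22 to 2.39). MH08g0468600 had 123 and 191 counts, 1.52-fold higher in library 2 (1.21 to 1.93), with an adjusted p of 0.0452 by the exact binomial test that lay between 0.0199 and 0.0837 over 5 alternatives and above 0.05 under 3 of them.

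**Figure D3:**
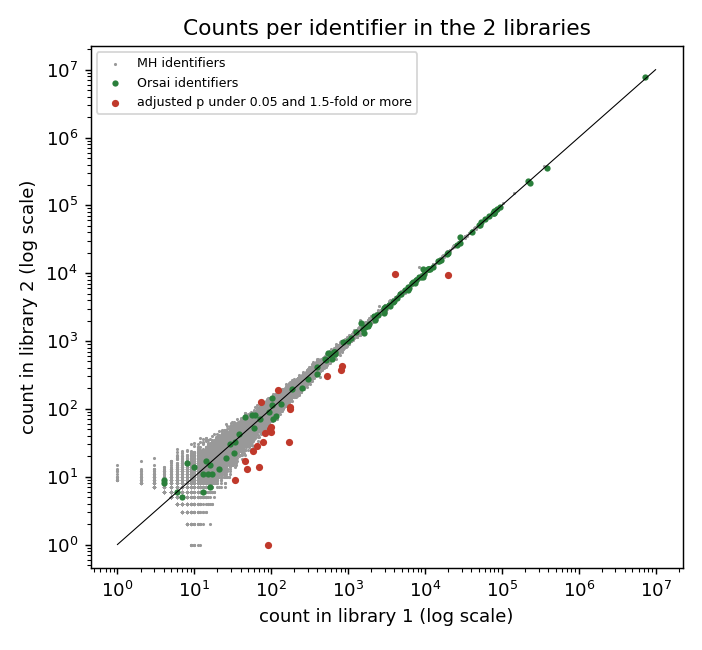
Counts of each tested identifier in library 1 (horizontal) and library 2 (vertical), both on log scales, with the diagonal of equal counts and points with a count of 0 not drawn. MH identifiers are grey, Orsai identifiers green, and the 22 identifiers with an adjusted p under 0.05 and 1.5-fold or more are red, 19 higher in library 1 and 3 in library 2.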

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

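The tests in this part were all chosen after the results were seen. Several kinds of signal lay outside the gene comparisons, or in 1 case outside the FPKM comparisons only, and each was far above the limit that a count of 0 allows. The shares given next are of the sum of gene counts and summary lines. Entries with more than a single alignment made up 27.7% in library 1 and 25.8% in library 2. Entries aligned without a counted feature made up 8.08% and 7.95%. Entries that were not aligned made up 6.15% and 4.31%. OrsaiCp60, which has no FPKM value and so entered only the count comparisons, had 28780 counts in library 1 and 28030 in library 2.

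The 22 identifiers that differed by 1.5-fold or more between the libraries were weighed against 3 technical explanations. A depth or scaling shift common to all identifiers was not seen. The median log2 ratio of the other tested identifiers was 0.024 when scaled by total counts alone, which do not centre it. A common trend with gene length was not seen either, since the median log2 ratios of the other identifiers in 10 length bins spanned 0.044. Both values leave out the 22, which are few among 19770 tested identifiers. Neither value can therefore decide on a cause that acts on few identifiers. More leftover ribosomal RNA in library 1 stays open. OrsaiPr was taken as ribosomal because its lengths of 122 and 1695 equal mitochondrial rrn5 and rrn18 of the reference table. Its remaining length, 3542, equals none there. The summed OrsaiPr counts were 690 and 337 (log2 ratio 1.06), but 3 of the 19 identifiers higher in library 1 are OrsaiPr themselves. That value therefore restates the pattern for them. The 19 had unequal ratios, with log2 values from 0.77 to 5.98 (homogeneity chi-square p = 1.4e-12). The OrsaiPr identifiers among them differed from each other, at 0.84, 1.41 and 5.98, so unequal ratios cannot decide on this cause. No biological explanation was tested, because the design has a single group.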

How the results depend on the processing

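The alternatives using MH identifiers only, or MH totals, and all those of the ends and middle result in the last part were chosen after seeing the data. No paired analysis was possible because the libraries form a single group. The count of differing identifiers was 134, with 189 under DESeq2 size factors (114 shared), 125 under total counts (92 shared), 113 without a count filter, 149 at 100 or more counts, and 84 among MH identifiers scaled by their own total (44 higher in library 1 and 40 in library 2, 80 shared). For single identifiers, 47 of 50 tested alternatives kept direction and call and 3, all of MH08g0468600, lost the call. Count filters leave each ratio as it was and rescaling shifts all ratios by a small common amount. The kept direction is therefore no check of these identifiers. Pearson r was 0.979 with a pseudocount of 0.1 and 0.9945 among expressed identifiers. The coefficient of variation was 3.99% with DESeq2 size factors, 3.66% without a filter and 3.60% for MH identifiers. DESeq2's median gene dispersion gave 0.01%, the tool's lower bound. Expressed identifiers numbered 6428 at an FPKM of 5, and 15868 at 0.5, 17168 at 10 counts, 13809 or 13955 with a single library and 15945 with FPKM rescaled to the MH total. Without Orsai identifiers the top 10 held 10.9% and the top 100 held 29.8%. The chromosome test kept its call with a chi-square of 704 to 801. The ends minus middle difference of 17.1 points was 20.1 to 21.9 at other floors, 17.5 to 17.7 with a single library and 21.05 without chromosomes 4, 9, 10 and 11, which is no check of it, because these had the smallest differences and leaving them out had to raise the mean. Among models whose length is not a multiple of 3 it was 3.47 (exact permutation p = 0.21) with the 10 positional bins set among those models, and 7.15 (p = 0.0024) with bins set over all identifiers, so that result depends on how the bins were set. Alternatives for gene lists and clock genes were not run.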

Other observations

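Every test in this part was chosen after the results were seen. The OrsaiCp lengths were set against the organelle genes of a japonica reference table, assembly ASM3414082v1, as a hypothesis about what these identifiers are. Of 64 OrsaiCp lengths, 54 equalled a plastid protein-coding length exactly and 6 a mitochondrial one. Of 54 OrsaiPp lengths, 41 equalled a mitochondrial protein-coding length and 4 a plastid one. The series may therefore hold plastid and mitochondrial genes, although a shared length does not name a gene. The length of OrsaiCp01, 1062, is shared by psbA and psbD in that table, so it was left unnamed.

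For 41 OrsaiCp identifiers the length matched a single plastid symbol. Grouped by that candidate symbol, 9 photosystem, cytochrome or ATP synthase candidates had a median FPKM of 3136 and 3041 in libraries 1 and 2 (mean FPKM of single identifiers from 206 to 15061). The 7 NADH dehydrogenase candidates had 904 and 914 (1.59 to 1994), and 7 other candidates had 510 and 501 (1.26 to 3964). The 14 ribosomal protein candidates had 43.2 and 36.4 (1.18 to 1974), and the 4 RNA polymerase candidates had 5.88 and 5.39 (0.253 to 51.1). The ranges overlap and the groups were not tested against each other. They leave out the 13 identifiers whose length matched several symbols, OrsaiCp01 among them. Reads with more than a single alignment were left uncounted in every group, so low levels in any group may be undercounts. The ribosomal group holds rps7 and rps15 candidates, for which that question is taken up next.

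OrsaiCp identifiers with few counts may be copies whose reads aligned to both and were left uncounted. The 18 identifiers that share their length with another had a median of 530 counts per kb, against 17160 for the other 46 (permutation p = 0.015), but this does not test copies: the 18 ran from 8.87 to 7170180 counts per kb, and 12 of them, OrsaiCp01 included, have a length that several symbols share. Among ribosomal protein candidates, here including lengths shared by several ribosomal symbols, 8 identifiers had the length of a gene with 2 rows in the reference table. Their median was 168 counts per kb, against 6934 for the other 10 (exact permutation p = 0.0086). The 8 hold only the lengths 273, 282 and 471, and 282 is shared by rpl23 and rps19. Copies of a gene are not independent units, so this p overstates the evidence. Low counts were not limited to the 8, since the lowest of the other 10 had 26.7 counts per kb. RNA polymerase candidates with a length of their own were also low. Sequence was not examined.

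With the identifier order of each chromosome cut into 10 bins of equal size, the expressed share averaged over both ends was higher than in the middle, although a single end lay below the middle on chromosome 4 (10.5% against 18.6%), chromosome 10 (9.19% against 11.1%) and chromosome 11 (8.10% against 9.62%). It was 31.1% ± 7.78 in the outer bins and 14.0% ± 4.06 in the middle ones (SD, n = 12 chromosomes), a difference of 17.1 ± 7.14 points, with the mean of both ends higher on 12 of 12 (exact permutation p = 0.00049). After the share expected from length bin and divisibility by 3 was subtracted, 12.01 ± 5.25 points stayed. With divisibility alone 13.2 points stayed and with length alone 14.3, so length as given is argued against as the whole cause. Models without untranslated regions stay open, because models with such regions can also have a length divisible by 3. That class therefore mixes both kinds of model. On average over the chromosomes it made up 70.6% and 65.3% of the outer bins and 84.8% and 79.9% of the middle ones. Windows of 200 identifiers varied 9.88 times as much as binomial sampling given the same strata (highest of 100 permutations 1.18). The same limit holds for that ratio. Reads lost in repeats stay open, as no count per gene shows them.

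Several versions of that comparison were run within each class of model, and they did not all give the same call. Among models whose length is a multiple of 3 the difference was 16.1 ± 6.87 points with bins set over all identifiers and 17.0 ± 5.95 with bins set among those models. Among the other models it was 7.15 ± 5.55 points (11 of 12 chromosomes, exact permutation p = 0.0024) with bins set over all identifiers, and 3.47 ± 8.99 (8 of 12, exact permutation p = 0.21) with bins set among those models, which was the version run first. With bins over all identifiers the classes differed by 8.93 ± 7.21 points (10 of 12, exact permutation p = 0.0034). Whether the pattern holds outside models with a length divisible by 3 is therefore unsettled.

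Neighbouring identifiers resembled each other. An MH identifier was expressed in 40.3% of cases when the previous one was, and in 18.1% when it was not (permutation p = 0.001, the smallest that 1000 permutations can give). The permutations shuffled identifiers over each whole chromosome. This p therefore does not separate a likeness of neighbours from the difference between ends and middle or from kinds of model. Models whose length is a multiple of 3 were expressed in 16.3% of 42429 cases and the others in 43.3% of 14712, but their median lengths were 993 and 2164. Within 10 length bins the others were higher in 8 and lower in 2, at 6.03% against 10.1% and 7.77% against 10.6%.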
